A study of Mus musculus with 14 samples.

How the data were processed

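RNA-seq counts of 14 libraries from mouse small intestinal epithelial cells were analysed: 3 of Cre-negative controls with floxed alleles of both genes (WT), 3 of ZKO (Villin-Cre, floxed Prkcz), 4 of LKO (Villin-Cre, floxed Prkci) and 4 of DKO (Villin-Cre, both). Per the labels, epithelial cells were released with EDTA from mice of 8 weeks and single-end, directional libraries were made from polyadenylated RNA. The groups were taken from the sample titles and genotypes; the description field calls the single knockouts double knockouts, against both, and was not used. The deposited table holds 1 raw count per gene and library, with genes given by symbol and no normalization applied; per the submitters' processing notes STAR and DESeq2 were used with genome build mm10, with neither versions nor the role of each tool stated. A second sheet of the deposited file holds 0 values and was left out.

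The values are whole numbers, 0 of them is zero, and the lowest is 1. In the 11 libraries without Y-linked reads the 44 values of 4 Y-linked genes had a mean of 1.5, of which 30 were exactly 1, and the Poisson chance of no zero at that mean is 1.5e-05. The deposited counts may therefore have had 1 added to each, which the labels do not state; a fit with every value lowered by 1 was run as an alternative. Symbols were matched to GENCODE mouse release 21 (GRCm38, the same assembly as mm10), 13226 by symbol and 415 by an older symbol, for coordinates and transcript lengths.

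Genes with low counts were removed with filterByExpr by group, which left 13432 and removed 322. Library sizes were normalized with TMM (factors from 0.893 to 1.28), and all 14 libraries were fitted together with edgeR 4.0.16 (quasi-likelihood F-test, robust), with R 4.3.3 and limma 3.58.1. The biological coefficient of variation was 0.262. Adjusted p-values are Benjamini-Hochberg values over the genes tested within a comparison, with a threshold of 0.05, and the SE of a log2 change is its size divided by the square root of F. Chance alone gives an unadjusted p under 0.05 to a share of about 0.05 of the genes tested. Log2 CPM values used a prior count of 2. CPM values are given as mean ± SD over the libraries of a group. The largest median log2 change of all genes in a comparison was -0.04. The labels give no batch, sex or litter, so the model held groups only. The 6 comparisons were tested with no correction across them: DKO, LKO and ZKO against WT, DKO against LKO, DKO against ZKO, and the interaction.

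The 25 gene lists were tested with camera (inter-gene correlation preset to 0.01), adjusted over the lists within a comparison, and again with a correlation estimated per list. Members past the threshold were counted over all genes tested and also when adjusted over the list alone. The lists were interferon response, MHC class I and class II antigen presentation, Paneth cell, goblet cell, enteroendocrine cell, tuft cell, intestinal stem cell, cell cycle, enterocyte brush border, proximal and distal small intestine, regenerative and YAP-associated, gastric-type metaplasia, antimicrobial and inflammation, T cell, B and plasma cell, myeloid cell, stroma with endothelium and nerve, unfolded protein response, immediate early and heat shock, oxidative phosphorylation, cholesterol synthesis, glutathione and xenobiotic defence, and polarity complexes and tight junctions. With an estimated correlation the calls that held were those of the cholesterol synthesis list in DKO and in LKO against WT. A list score is the mean log2 CPM of the members minus the WT mean.

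Groups, comparisons, tests, lists, the naming rule and the first set of alternatives were chosen before the data were examined. The rule named Prkci and Prkcz in every comparison. It named up to 6 genes that rose and 6 that fell against WT, or 4 and 4 in the other comparisons, with the largest log2 change among called genes of average log2 CPM of at least 1. Their libraries had to be without overlap between the groups, which was not asked of the interaction, and gene models without a proper name and antigen receptor segments were left out. From each list it named up to 4 called members with the smallest adjusted p, or 2 members given as values where none was called. Fewer genes are named in the text, and genes named outside the rule are marked as such.

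That first set held DESeq2 size factors, no filter on low counts, DESeq2 1.42.0 (Wald test), limma-voom with and without sample quality weights, the libraries of the 2 groups alone, a 2-fold threshold, an adjusted p under 0.1, each library left out in turn, and for the lists an estimated correlation, fry and camera on ranks. Chosen after seeing the data were every value lowered by 1, a term for the 3 libraries that tilt toward short transcripts or leaving these out, and a term for the 3 libraries with Y-linked reads or leaving these out. A library counted as tilted when its Spearman trend with transcript length was under -0.2, and as having Y-linked reads when Ddx3y exceeded 5 CPM. The trend correlated, across genes, the longest transcript length with the log2 of CPM plus 1, minus the gene's mean over all libraries.

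The test was run on simulated data made from these libraries, with 100 genes changed 2-fold and 100 changed 4-fold. In DKO against WT it recovered 46 of them at 2-fold and 85 at 4-fold with 2 false calls. In ZKO against WT it recovered 30 and 78 with 4 false calls, and in DKO against LKO 43 and 83 with 8 false calls. A raised cell cycle list ranked 1 among the lists, and 0 others passed the threshold. The simulated genes varied independently of each other, so this does not check the list test where members vary together. Library totals ranged from 19237330 to 28340260 counts, so counting error is small for most genes, and the spread between mice sets the precision. Replicates differed by 21.3 to 301 times the chi-square per gene that counting error alone gives. Calculations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 drew the plots.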

Results

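Polyadenylated RNA of epithelial cells from the small intestine was sequenced in 14 libraries, each from a C57BL/6 mouse of 8 weeks. The mice carried floxed alleles of the atypical protein kinase C genes Prkci (PKCλ/ι), Prkcz (PKCζ) or both. All but the controls also carried the Villin-Cre transgene, which deletes floxed alleles in the intestinal epithelium, so each comparison with WT is also one of Cre with none. There were 3 control libraries without Cre (WT), 3 that lost PKCζ (ZKO), 4 that lost PKCλ/ι (LKO) and 4 that lost both (DKO). Each library is named by its group and mouse number. Library totals were 28340260, 27267114 and 26862283 counts in WT_216, WT_254 and WT_259. They were 20942058, 24565459 and 19237330 in ZKO_19, ZKO_20 and ZKO_22. They were 23367815, 27093459, 23965314 and 22837409 in LKO_224, LKO_250, LKO_251 and LKO_256. They were 24016295, 25245629, 24367587 and 24481624 in DKO_223, DKO_231, DKO_240 and DKO_260. A filter on low counts left 13432 genes for testing.

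Libraries also differed in ways that the groups do not describe. Counts in WT_216, LKO_224 and DKO_223 tilted toward short transcripts. The tilt is relative to the other libraries, as each gene's log2 value was taken minus its mean over all libraries. Spearman trends of these differences with transcript length across genes were -0.216, -0.433 and -0.407 in the 3 libraries. Reads of Y-linked genes appeared in ZKO_19, ZKO_20 and DKO_240, with Ddx3y at 36.4, 37.7 and 38.9 CPM (counts scaled to the library total). The other 11 libraries, all of WT and LKO among them, lacked them, and the labels do not give the sex of the mice. Xist was at 0.143, 0.285 and 0.369 CPM in ZKO_19, ZKO_20 and DKO_240, and at 96.4 to 376 CPM in the other 11. By both measures ZKO_19, ZKO_20 and DKO_240 came from males and the other 11 from females. Comparisons that hold ZKO or DKO are thus in part also comparisons of sex. The mouse numbers of ZKO lay apart from those of the other groups. A separate colony or litter is therefore possible in each comparison that holds ZKO, and was not tested. The first principal component held 41.9% of the variance. It placed WT and ZKO libraries from -52.0 to -39.7 and most LKO and DKO libraries from 30.5 to 55.1, with LKO_251 and DKO_231 between them at 0.15 and 1.90.

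The targeted genes were examined first. From here on, CPM values were scaled to library totals corrected by the TMM factors. Prkcz (ENSMUSG00000029053.16; GRCm38 chromosome 4, 155260129 to 155361361) was at 63.2, 103 and 92.6 CPM in the WT libraries, and at 28, 37.7 and 28.1 in ZKO. It was at 39.8, 38.7, 71.5 and 48.0 CPM in LKO and at 26.8, 43.0, 16.5 and 34.3 in DKO. In DKO it fell by 1.52 on the log2 scale (SE 0.30, adjusted p = 0.00734). Its log2 change in ZKO was -1.46 (SE 0.32, adjusted p = 0.133), which did not pass the threshold, although all 3 ZKO libraries lay below every WT library. That difference passed with DESeq2, with sample quality weights and in a fit of the 2 groups alone, at log2 changes of -1.46, -1.59 and -1.47. In LKO, where Prkcz was not targeted, its log2 change was -0.80 (SE 0.29, adjusted p = 0.119), and without LKO_251 it was -1.03 and passed.

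Prkci (ENSMUSG00000037643.14; GRCm38 chromosome 3, 30995747 to 31052959) was at 47.3, 47.9 and 48.7 CPM in WT and at 48.4, 47.8 and 49.4 in ZKO. It was at 41.1, 47.5, 43.9 and 43.8 CPM in LKO and at 45.7, 44.5, 50.4 and 48.3 in DKO. Its log2 change from WT was -0.12 (SE 0.10, adjusted p = 0.488) in LKO and -0.02 (SE 0.10, adjusted p = 0.904) in DKO, and neither passed the threshold. Whole-gene counts do not check an exon deletion, since a transcript that lacks the deleted exons is still counted.

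**Figure D1:**
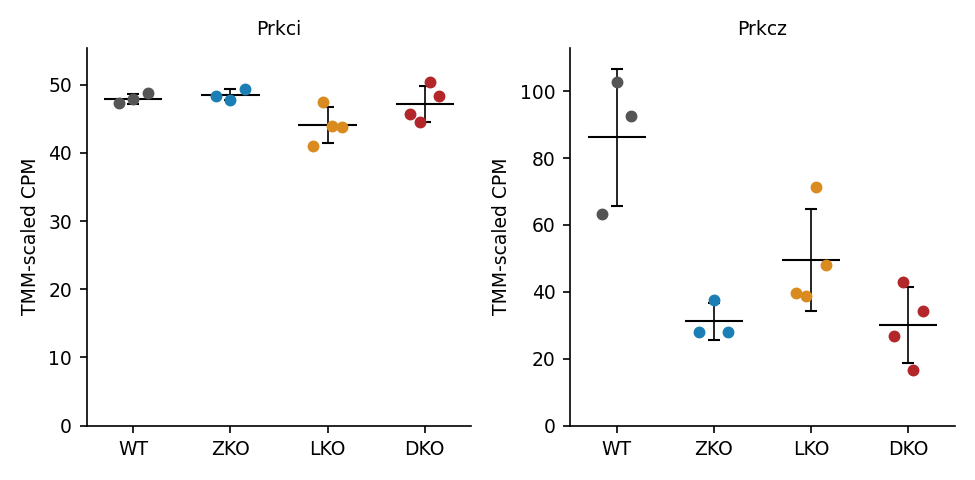
Prkci and Prkcz in CPM (linear axis from 0) for each library of the 4 groups; dots are libraries and the lines with bars are the group mean ± SD. Prkci means lie between 44.1 and 48.5 CPM, and Prkcz means between 30.1 in DKO and 86.2 in WT.

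DKO against WT addresses what the loss of both atypical PKCs does to the epithelium. In DKO, 18 of 25 cholesterol synthesis and 15 of 31 regenerative genes rose, and 11 of 14 Paneth cell, 8 of 21 tuft cell and 7 of 35 brush border genes fell. With an estimated correlation the cholesterol list kept its call (adjusted p = 0.0425) and the other 4 lists lost theirs (adjusted p = 0.143, 0.143, 0.678 and 0.678). The annexin gene Anxa10 (GRCm38 chromosome 8, 62057042 to 62123150) went from 0.0802 ± 0.00225 CPM (mean ± SD, n = 3) in WT to 43.3 ± 35.4 (n = 4) in DKO. Its log2 change was 8.99 (SE 1.30, adjusted p = 0.00151), but the WT libraries held only a few counts of it, so the size of this change is uncertain. Nes, which encodes the intermediate filament nestin, rose by 5.69 (SE 0.52, adjusted p = 0.000136) and Anxa1 by 6.25 (SE 0.87, adjusted p = 0.00123). Among the largest falls were Sypl2, with a log2 change of -5.12 (SE 0.74, adjusted p = 0.00151), and the alpha-defensin genes Defa3 and Defa26, at -4.93 and -4.64 (adjusted p = 0.00430 and 0.00316).

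Of 25 cholesterol synthesis genes, 18 rose in DKO and 7 were not called, and 21 rose when adjusted over the list alone. The list's median log2 change was 1.31 (adjusted p = 1.8e-22), with adjusted p = 0.0425 under an estimated correlation. The list score of all 4 DKO libraries was above that of every WT library. The sterol pathway enzyme genes Fdps, Lss and Pmvk rose by 1.94, 1.70 and 1.53 on the log2 scale (adjusted p = 0.000361, 0.000346 and 0.000346). Of 31 regenerative and YAP-associated genes, 15 rose and 1 fell, and 18 and 2 did so when adjusted over the list alone. Their median log2 change was 1.83 (adjusted p = 4.1e-12, or adjusted p = 0.143 with an estimated correlation). Clu (GRCm38 chromosome 14, 65968483 to 65981547), a marker of revival stem cells, went from 2.35 ± 0.776 to 61.1 ± 27.4 CPM, a log2 change of 4.69 (SE 0.50, adjusted p = 0.000307). Il1rn, the interleukin 1 receptor antagonist gene, rose by 4.54 (SE 0.42, adjusted p = 0.000136), and Anxa5 and the keratin gene Krt7 by 2.16 and 1.79 (adjusted p = 0.000406 and 0.00100).

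Of 14 Paneth cell genes, 11 fell and 3 were not called, with 11 falling when adjusted over the list alone. As a list they had a median log2 change of -3.81 (adjusted p = 4.2e-12, and adjusted p = 0.143 with an estimated correlation). Itln1, which encodes an intelectin that binds microbial glycans, went from 1143 ± 585 CPM in WT to 111 ± 122 in DKO, a log2 change of -3.37 (SE 0.61, adjusted p = 0.00521). Its call ended in a fit of the 2 groups alone and without the 3 tilted libraries (adjusted p up to 0.0519 over the alternatives). Defa17 changed by -4.36 (SE 0.82, adjusted p = 0.00589). The defensin genes are close paralogs whose reads can be shared, so values of single members are uncertain. Of 21 tuft cell genes, 8 fell and 13 were not called, with 15 falling when adjusted over the list alone. Across the list the median log2 change was -1.40 (adjusted p = 8.6e-08, and adjusted p = 0.678 with an estimated correlation). Pou2f3, the transcription factor gene that specifies tuft cells, had a log2 change of -1.54 (SE 0.39, adjusted p = 0.0215). Its call ended without WT_216, WT_254, WT_259 or DKO_240 (adjusted p up to 0.0627).

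Of 35 brush border genes, 7 fell and 28 were not called, with 13 falling when adjusted over the list alone. For the whole list the median log2 change was -0.69 (adjusted p = 4.2e-07, or adjusted p = 0.678 with an estimated correlation). The peptidase gene Dpp4 changed by -1.49 (SE 0.30, adjusted p = 0.00908). Of 27 antimicrobial and inflammation genes, 2 rose and 5 fell, against 3 and 11 when adjusted over the list alone. The list as a whole had a median log2 change of -0.63 (adjusted p = 0.00806, and adjusted p = 0.678 with an estimated correlation). This list's call ended without WT_254 or WT_259 (adjusted p up to 0.123). Reg3a, which encodes a bactericidal lectin, changed by -2.16 (SE 0.46, adjusted p = 0.0111), and Mptx1, a pentraxin gene, by -4.07 (SE 0.65, adjusted p = 0.00278).

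Stem cell and Wnt target genes moved apart, with 5 of 26 rising and 6 falling, the same numbers as when adjusted over the list alone. The list itself did not pass the threshold (adjusted p = 0.666). Cd44 rose by 2.17 (SE 0.31, adjusted p = 0.00130), while the Wnt target Axin2 changed by -0.89 (SE 0.17, adjusted p = 0.00710) and Tnfrsf19 by -2.12 (SE 0.42, adjusted p = 0.00858). The Axin2 and Tnfrsf19 calls ended in a fit of the 2 groups alone (adjusted p = 0.0608 and 0.0627, the highest over the alternatives), and that of Tnfrsf19 also without the 3 tilted libraries or the 3 with Y-linked reads. All 40 cell cycle genes had a positive log2 change, and 3 were called, both over all genes and when adjusted over the list alone. The list test gave adjusted p = 1.7e-05 at a median log2 change of 0.51, and adjusted p = 0.832 with an estimated correlation. Of 25 glutathione and xenobiotic defence genes 6 rose and 1 fell, or 7 and 3 when adjusted over the list alone. The list's median log2 change was 0.49 (adjusted p = 0.0221), with adjusted p = 0.678 under an estimated correlation. The glutathione call ended without WT_254 or WT_259 (adjusted p up to 0.0807). Gsta4, a glutathione transferase gene, rose by 2.21 (SE 0.33, adjusted p = 0.00190). Cldn2, which encodes a claudin that forms paracellular cation channels, rose by 1.60 (SE 0.28, adjusted p = 0.00412), within a polarity and junction list that did not pass the threshold (adjusted p = 0.352).

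Markers of other cells moved as well. Of 14 B and plasma cell genes 3 were lower in DKO, or 8 when adjusted over the list alone. Their median log2 change was -2.27 (adjusted p = 0.00176, or adjusted p = 0.751 with an estimated correlation). The list score of WT_216 was -1.24, within the DKO range of -1.99 to -0.46, against 0.49 and 0.75 in WT_254 and WT_259. The T cell list was also lower. As a list they had a median log2 change of -0.58 (adjusted p = 0.0221, and adjusted p = 0.923 with an estimated correlation). The T cell call ended without WT_216, WT_259 or DKO_260 (adjusted p up to 0.741). Genes of the ileum were lower, with 2 of 15 called and 5 when adjusted over the list alone. Across the list the median log2 change was -0.91 (adjusted p = 0.00388, and adjusted p = 0.678 with an estimated correlation). Among 22 goblet cell genes 1 rose and 1 fell. For the whole list the median log2 change was -0.34 (adjusted p = 0.0286, or adjusted p = 0.893 with an estimated correlation). The goblet call ended without WT_216, WT_254, DKO_223 or DKO_260 (adjusted p up to 0.287). The interferon response (adjusted p = 0.398), MHC class I (adjusted p = 0.666), MHC class II (adjusted p = 0.637) and enteroendocrine cell (adjusted p = 0.352) lists did not pass the threshold. Neither did the proximal small intestine (adjusted p = 0.736), myeloid (adjusted p = 0.258), and stroma, endothelium and nerve (adjusted p = 0.782) lists, nor the 5 measured gastric-type genes (adjusted p = 0.715). The unfolded protein response (adjusted p = 0.340), immediate early and heat shock (adjusted p = 0.832) and oxidative phosphorylation (adjusted p = 0.715) lists did not pass either.

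By the edgeR quasi-likelihood test at an adjusted p under 0.05, 1059 genes were higher and 895 lower in DKO than in WT, 1954 in all. Of these, 1037 changed at least 2-fold. The DKO and WT libraries did not overlap in 3300 genes (24.6% of those tested, where chance gives 5.71%). Single libraries moved the count, which was 1073 without WT_216, 573 without WT_254, 634 without WT_259, 1258 without DKO_223, 3088 without DKO_231 and 898 without DKO_240. Of the 72 called genes chosen by the naming rule, 36 kept their call without each library in turn. A fit of the 2 groups alone called 243 genes higher and 147 lower. With a term for the tilt the total was 4053 and without the tilted libraries 827, and with a term for Y-linked reads it was 1117 and without the libraries that hold them 388. DESeq2 called 2854 genes, and limma-voom 1873, or 2479 with sample quality weights.

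**Figure D2:**
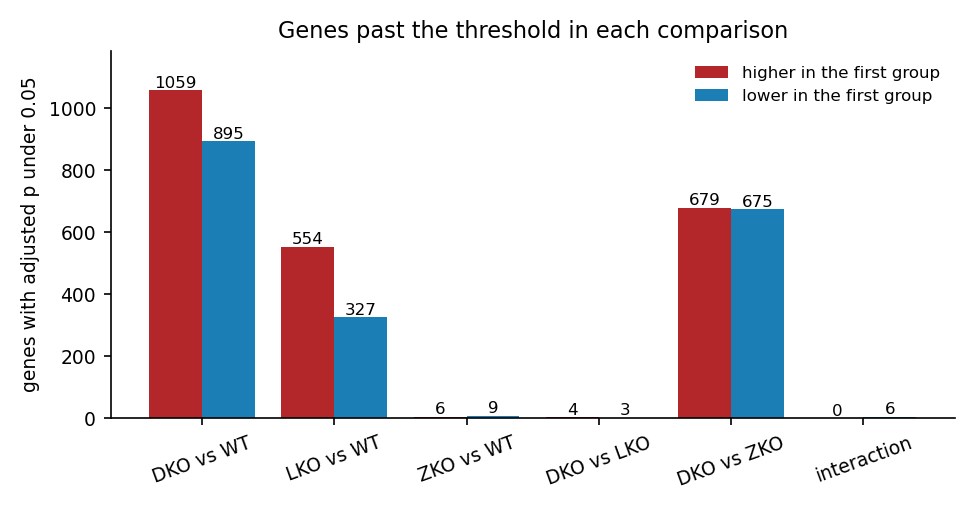
Genes with an adjusted p under 0.05 (vertical axis, number of genes from 0) in each of the 6 comparisons, split into higher and lower. DKO against WT has 1059 higher and 895 lower genes, and ZKO against WT has 6 higher and 9 lower.

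LKO against WT addresses the loss of PKCλ/ι alone. In LKO, 14 of 21 tuft cell and 10 of 14 Paneth cell genes fell, and 16 of 25 cholesterol synthesis and 12 of 31 regenerative genes rose. With an estimated correlation the cholesterol list kept its call (adjusted p = 0.0407) and the tuft, Paneth and regenerative lists lost theirs (adjusted p = 0.132, 0.175 and 0.132). All 21 tuft cell genes fell when adjusted over the list alone. The list as a whole had a median log2 change of -2.12 (adjusted p = 4.2e-22, and adjusted p = 0.132 with an estimated correlation). Pou2f3 went from 2.10 ± 0.332 CPM (mean ± SD, n = 3) in WT to 0.221 ± 0.105 (n = 4) in LKO, a log2 change of -3.25 (SE 0.44, adjusted p = 0.00105). Dclk1, a kinase gene that marks tuft cells, changed by -2.92 (SE 0.47, adjusted p = 0.00335), and the leukotriene synthesis gene Alox5 by -3.27 (SE 0.46, adjusted p = 0.00147). Of 14 Paneth cell genes 10 fell, or 12 when adjusted over the list alone. The list test gave adjusted p = 1.1e-11 at a median log2 change of -3.34, and adjusted p = 0.175 with an estimated correlation. Defa21 went from 378 ± 165 to 7.82 ± 7.94 CPM, a log2 change of -5.60 (SE 1.17, adjusted p = 0.0132). Of 25 cholesterol synthesis genes 16 rose, or 21 when adjusted over the list alone. The list's median log2 change was 0.91 (adjusted p = 4.2e-22), with adjusted p = 0.0407 under an estimated correlation. Sqle, the squalene epoxidase gene, rose by 1.58 (SE 0.25, adjusted p = 0.00273).

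Of 31 regenerative and YAP-associated genes 12 rose and 1 fell in LKO, or 14 and 1 when adjusted over the list alone. Their median log2 change was 0.95 (adjusted p = 1.1e-11, or adjusted p = 0.132 with an estimated correlation). Anxa10 rose by 8.30 (SE 1.29, adjusted p = 0.00273) and Clu by 3.60 (SE 0.48, adjusted p = 0.00101), and the Anxa10 call ended without the 3 tilted libraries (adjusted p = 0.0615). All 40 cell cycle genes had a positive log2 change, with 5 called over all genes and 25 when adjusted over the list alone. As a list they had a median log2 change of 0.69 (adjusted p = 1.8e-12, and adjusted p = 0.568 with an estimated correlation). Of 25 glutathione and xenobiotic defence genes 6 rose and 1 fell, or 14 and 1 when adjusted over the list alone. Across the list the median log2 change was 0.69 (adjusted p = 0.000188, and adjusted p = 0.230 with an estimated correlation). Gsta4 rose by 2.32 (SE 0.34, adjusted p = 0.00169), and Gstm2, another glutathione transferase gene, changed by -1.32 (SE 0.23, adjusted p = 0.00483). Among 26 stem cell genes 4 rose and 3 fell, or 6 and 4 when adjusted over the list alone, and the list did not pass the threshold (adjusted p = 0.442). Olfm4, a product of crypt base columnar cells, went from 332 ± 76.1 to 91.3 ± 17.6 CPM, a log2 change of -1.86 (SE 0.36, adjusted p = 0.00909), and lost its call without the 3 tilted libraries (adjusted p = 0.0593). Lpo, which encodes lactoperoxidase, rose by 6.34 (SE 0.77, adjusted p = 0.000686).

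B and plasma cell markers were lower in LKO, with 3 of 14 called and 9 when adjusted over the list alone. For the whole list the median log2 change was -2.33 (adjusted p = 0.000266, or adjusted p = 0.790 with an estimated correlation). WT_216, with a list score of -1.24, lay within the LKO range of -1.65 to -0.94, and WT_254 and WT_259 at 0.49 and 0.75. The T cell list was lower as well. The list as a whole had a median log2 change of -0.75 (adjusted p = 0.00839, and adjusted p = 0.937 with an estimated correlation). The T cell call ended without WT_259 or LKO_250 (adjusted p up to 0.112). The brush border list was lower, and the smallest adjusted p of a member was 0.138, for Apoc3. The list test gave adjusted p = 0.000359 at a median log2 change of -0.43, and adjusted p = 0.937 with an estimated correlation. In the proximal list 2 genes rose and 1 fell. The list's median log2 change was -0.73 (adjusted p = 0.0150), with adjusted p = 0.835 under an estimated correlation. The proximal call ended without WT_216 or LKO_256 (adjusted p up to 0.11).

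In total 554 genes were higher and 327 lower in LKO than in WT, 881 in all and 610 at least 2-fold. The LKO and WT libraries did not overlap in 3060 genes (22.8% of those tested, where chance gives 5.71%). The count was 290 without WT_216, 379 without WT_254, 383 without WT_259, 315 without LKO_250, 1583 without LKO_251 and 373 without LKO_256. Of the 53 called genes chosen by the naming rule, 33 kept their call without each library in turn. Without the 3 tilted libraries 121 genes were higher and 80 lower, while a term for the tilt gave 1127 and 703. DESeq2 called 1053 and 530, limma-voom 478 and 345, and limma-voom with sample quality weights 2364 and 2387.

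ZKO against WT addresses the loss of PKCζ alone, and 15 genes passed the threshold. Mt1 (GRCm38 chromosome 8, 94179082 to 94180327), a metallothionein gene, went from 53.8 ± 9.52 CPM (mean ± SD, n = 3) in WT to 532 ± 20.4 (n = 3) in ZKO, a log2 change of 3.31 (SE 0.33, adjusted p = 0.000661). Cyp1a1 (GRCm38 chromosome 9, 57687928 to 57703824), a target of the aryl hydrocarbon receptor, went from 0.0931 ± 0.0203 to 6.31 ± 3.35 CPM, a log2 change of 6.01 (SE 0.53, adjusted p = 0.000310). The WT libraries held only a few counts of Cyp1a1, so the size of this change is uncertain. The carboxylesterase gene Ces1f rose by 2.18 (SE 0.26, adjusted p = 0.00308). Reg3b, which encodes an antimicrobial lectin, went from 18956 ± 3272 to 3163 ± 612 CPM, a log2 change of -2.58 (SE 0.42, adjusted p = 0.0293). Tifa, an adaptor gene of the ALPK1 pathway to NF-κB, changed by -1.79 (SE 0.25, adjusted p = 0.0129) and the kinase gene Ptk6 by -1.35 (SE 0.20, adjusted p = 0.0190). Ddx60, an interferon-induced helicase gene, changed by -2.33 (SE 0.36, adjusted p = 0.0243).

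The interferon response list was lower in ZKO, where 55 of 56 members had a negative log2 change. Over all genes 1 member was called, and 38 were when adjusted over the list alone. Their median log2 change was -1.37 (adjusted p = 3.4e-42, or adjusted p = 0.0685 with an estimated correlation). Values of members that did not pass over all genes were -2.40 (SE 0.56, adjusted p = 0.154) for Isg15 and -2.44 (SE 0.53, adjusted p = 0.124) for Ifit1. The list score relative to the WT mean was -0.93, -1.33 and -1.35 in ZKO_19, ZKO_20 and ZKO_22. It was -0.77, 0.50 and 0.27 in WT_216, WT_254 and WT_259. MHC class I genes were lower too, with 5 of 24 called when adjusted over the list alone. As a list they had a median log2 change of -0.54 (adjusted p = 6.0e-13, and adjusted p = 0.0685 with an estimated correlation). The smallest adjusted p of an MHC class I gene over all genes was 0.205, for H2-D1. Antimicrobial genes were lower, with 1 of 27 called over all genes, and 7 lower and 1 higher when adjusted over the list alone. Across the list the median log2 change was -0.55 (adjusted p = 4.0e-07, and adjusted p = 0.108 with an estimated correlation).

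Tuft cell genes were higher in ZKO, with all 21 log2 changes positive and 2 called when adjusted over the list alone. For the whole list the median log2 change was 0.86 (adjusted p = 1.4e-09, or adjusted p = 0.249 with an estimated correlation). Further lists passed with the preset correlation and lost their call with an estimated correlation, and for each the median log2 change is given with both adjusted p-values, the estimated one last. Higher were the glutathione (0.34, adjusted p = 2.5e-07 and 0.0685), cholesterol synthesis (0.30, adjusted p = 6.3e-07 and 0.212), stem cell (0.44, adjusted p = 2.3e-06 and 0.249) and cell cycle lists (0.27, adjusted p = 3.7e-05 and 0.715). So were the 5 measured gastric-type genes (1.15, adjusted p = 0.00218 and 0.0685) and the B and plasma cell (0.87, adjusted p = 0.0156 and 0.715) and Paneth cell lists (0.45, adjusted p = 0.0334 and 0.715). Lower were the unfolded protein response (-0.21, adjusted p = 0.000939 and 0.230), T cell (-0.62, adjusted p = 0.00326 and 0.756) and myeloid lists (-0.38, adjusted p = 0.0250 and 0.715). So were the brush border (-0.17, adjusted p = 0.0307 and 0.756) and oxidative phosphorylation lists (-0.14, adjusted p = 0.0307 and 0.756).

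Single libraries ended several of these list calls. The Paneth call ended without WT_259 or ZKO_22 (adjusted p up to 0.492) and the cell cycle call without ZKO_19 (adjusted p = 0.0761). The brush border call ended without WT_254 or ZKO_19 (adjusted p up to 0.41) and the myeloid call without WT_259 or ZKO_22 (adjusted p up to 0.0954). The oxidative phosphorylation call ended without ZKO_20 and turned direction without WT_216 (adjusted p = 0.643). The B and plasma cell call ended without WT_216 and turned direction without ZKO_20 (adjusted p = 0.738). With a term for Y-linked reads the brush border list turned direction and passed as higher (adjusted p = 0.00299). The cell cycle, B and plasma cell and oxidative phosphorylation lists turned direction without passing (adjusted p = 0.264, 0.0648 and 0.552). Without the 3 libraries with Y-linked reads the B and plasma cell list passed as lower (adjusted p = 0.0289), and the cell cycle, brush border and oxidative phosphorylation calls ended (adjusted p = 0.104, 0.360 and 0.104). Oxidative phosphorylation also turned direction with a term for the tilt or without the tilted libraries (adjusted p = 0.217 and 0.600).

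In all, 6 genes were higher and 9 lower in ZKO than in WT, with 1090 at an unadjusted p under 0.05. The ZKO and WT libraries did not overlap in 3124 genes (23.3% of those tested, where chance gives 10%). DESeq2 called 55 genes higher and 112 lower, and the fit of the 2 groups alone 41 and 65. The count was 55 without WT_216, 4 without WT_254, 5 without WT_259, 4 without ZKO_19, 5 without ZKO_20 and 4 without ZKO_22. The calls of Mt1, Ces1f and Cyp1a1 held without each library in turn. Those of Reg3b, Tifa, Ptk6 and Ddx60 ended when WT_254, WT_259, ZKO_19, ZKO_20 or ZKO_22 was left out alone (adjusted p up to 0.225, 0.107, 0.123 and 0.179). Y-linked reads were present in ZKO_19 and ZKO_20 and in no WT library, and with a term for them 3 genes passed upward and 0 downward, against 1 and 0 without the libraries that hold them. Limma-voom called 14 genes, and 453 higher and 601 lower with sample quality weights. The total was 55 with a term for the tilt and 130 without the tilted libraries.

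DKO against LKO addresses what the loss of PKCζ adds once PKCλ/ι is lost. Prkcz itself had a log2 change of -0.72 here (adjusted p = 0.266). It did not pass the threshold, and its libraries overlapped between the groups. Tifa went from 233 ± 60.8 CPM (mean ± SD, n = 4) in LKO to 65.6 ± 15.9 (n = 4) in DKO, a log2 change of -1.83 (SE 0.22, adjusted p = 0.0121). Ptk6 changed by -1.11 (SE 0.17, adjusted p = 0.0382), and like Tifa it also fell in ZKO against WT. Bmyc rose by 4.13 (SE 0.65, adjusted p = 0.0382) and the transcription factor gene Mycn by 1.95 (SE 0.27, adjusted p = 0.0352). Ager and Snhg20 rose by 1.54 and 0.98 (adjusted p = 0.0382 for both). Lgi4, named after its value was seen, changed by -2.80 (SE 0.44, adjusted p = 0.0382). Antimicrobial genes were lower in DKO than in LKO, with 8 of 27 called when adjusted over the list alone. The list as a whole had a median log2 change of -0.58 (adjusted p = 8.7e-09, and adjusted p = 0.243 with an estimated correlation). Tuft cell genes were higher, with 8 of 21 called when adjusted over the list alone. The list test gave adjusted p = 7.5e-07 at a median log2 change of 0.88, and adjusted p = 0.643 with an estimated correlation. Goblet (-0.36, adjusted p = 3.5e-06 and 0.643 with an estimated correlation), interferon (-0.38, adjusted p = 5.1e-06 and 0.643) and ileal lists (-0.59, adjusted p = 1.3e-05 and 0.592) were lower.

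These 7 genes, 4 higher and 3 lower, passed the edgeR test between DKO and LKO without further terms, and 1794 had an unadjusted p under 0.05. The libraries did not overlap in 708 genes (5.27% of those tested, where chance gives 2.86%). DESeq2 called 215 genes higher and 229 lower, and an edgeR fit of the 2 groups alone called 0. The edgeR fit with a term for the tilt called 183 higher and 171 lower, these 7 among them, against 2 genes without the tilted libraries, 2 with a term for Y-linked reads and 1 without the libraries that hold them. Limma-voom called 8 genes, and 43 with sample quality weights. The count was 531 without DKO_231, 16 without LKO_251, 1 without LKO_224, 4 without DKO_223 and 3 without DKO_240. It was 0 without LKO_250, LKO_256 or DKO_260. None of the calls of Tifa, Ptk6, Bmyc, Mycn, Ager and Snhg20 held without each library in turn (adjusted p up to 0.0687 for Tifa and 0.144 for Ptk6, both without DKO_260). A further 11 lists passed with the preset correlation, and 0 of the 16 did with an estimated correlation.

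DKO against ZKO addresses what the loss of PKCλ/ι adds once PKCζ is lost. In DKO, 19 of 21 tuft cell and 11 of 14 Paneth cell genes fell against ZKO, and 16 of 31 regenerative, 13 of 25 cholesterol synthesis and 20 of 56 interferon response genes rose. With an estimated correlation these lists lost their calls (adjusted p = 0.0951, 0.0951, 0.0951, 0.0951 and 0.457). Adjusted over the list alone, all 21 tuft cell genes fell. The list's median log2 change was -2.28 (adjusted p = 9.4e-21), with adjusted p = 0.0951 under an estimated correlation. Pou2f3 went from 4.71 ± 0.552 CPM (mean ± SD, n = 3) in ZKO to 0.720 ± 0.397 (n = 4) in DKO, a log2 change of -2.70 (SE 0.38, adjusted p = 0.00107). Of 14 Paneth cell genes 11 fell, or 12 when adjusted over the list alone. Their median log2 change was -4.31 (adjusted p = 1.8e-16, or adjusted p = 0.0951 with an estimated correlation). Lyz1, the Paneth cell lysozyme gene, went from 3018 ± 295 to 208 ± 221 CPM, a log2 change of -3.86 (SE 0.65, adjusted p = 0.00273). Of 26 stem cell genes 6 fell and 2 rose, or 8 and 2 when adjusted over the list alone. As a list they had a median log2 change of -0.35 (adjusted p = 0.000587, and adjusted p = 0.469 with an estimated correlation). Lgr5, a receptor gene that marks crypt base columnar cells, changed by -2.74 (SE 0.51, adjusted p = 0.00515).

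Of 31 regenerative and YAP-associated genes 16 rose in DKO against ZKO, or 20 with 2 falling when adjusted over the list alone. Across the list the median log2 change was 1.74 (adjusted p = 2.8e-15, and adjusted p = 0.0951 with an estimated correlation). Clu rose by 4.99 (SE 0.51, adjusted p = 0.000197). Of 56 interferon response genes 20 rose, or 34 when adjusted over the list alone. For the whole list the median log2 change was 1.28 (adjusted p = 6.1e-13, or adjusted p = 0.457 with an estimated correlation). Cxcl9, a chemokine gene induced by interferon gamma, rose by 2.35 (SE 0.36, adjusted p = 0.00183) and the guanylate-binding protein gene Gbp7 by 2.48 (SE 0.49, adjusted p = 0.00738). Of 24 MHC class I genes 5 rose, or 10 when adjusted over the list alone. The list as a whole had a median log2 change of 0.41 (adjusted p = 0.000183, and adjusted p = 0.457 with an estimated correlation). H2-D1 rose by 1.00 (SE 0.19, adjusted p = 0.00620). Of 25 cholesterol synthesis genes 13 rose and 1 fell, or 17 and 1 when adjusted over the list alone. The list test gave adjusted p = 1.1e-12 at a median log2 change of 0.81, and adjusted p = 0.0951 with an estimated correlation. The phospholipase gene Pla2g4c went from 288 ± 131 CPM in ZKO to 1.34 ± 1.71 in DKO, a log2 change of -7.72 (SE 0.94, adjusted p = 0.000437), and Cyp1a1 changed by -6.90 (SE 0.51, adjusted p = 2.9e-05). Counts of Cyp1a1 were few in DKO, so the size of its change is uncertain.

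B and plasma cell markers were lower in DKO than in ZKO, with 8 of 14 called and 9 when adjusted over the list alone. The list's median log2 change was -3.23 (adjusted p = 2.2e-06), with adjusted p = 0.457 under an estimated correlation. List scores were 0.41, 1.92 and -0.45 in ZKO_19, ZKO_20 and ZKO_22. That of ZKO_22 was level with DKO_240, the highest of DKO at -0.46. The brush border (-0.48, adjusted p = 0.000164 and 0.762 with an estimated correlation), ileal (-0.92, adjusted p = 0.00183 and 0.469) and goblet lists (-0.22, adjusted p = 0.0398 and 0.912) were lower and the enteroendocrine list higher (0.34, adjusted p = 0.0398 and 0.762). The goblet call ended without ZKO_22, DKO_223 or DKO_260 (adjusted p up to 0.315) and the enteroendocrine call without ZKO_20, DKO_223, DKO_231 or DKO_240 (adjusted p up to 0.113). In total 679 genes were higher and 675 lower, 1354 in all and 939 at least 2-fold. The DKO and ZKO libraries did not overlap in 3615 genes (26.9% of those tested, where chance gives 5.71%). The count was 718 without ZKO_19, 488 without ZKO_20, 535 without ZKO_22, 891 without DKO_223 and 2220 without DKO_231. A fit of the 2 groups alone called 316 genes higher and 387 lower, and one with a term for the tilt 1101 and 1024. Without the 3 libraries with Y-linked reads, which leaves a single ZKO library, edgeR called 0 genes higher and 11 lower, against 3828 at an unadjusted p under 0.05 in all libraries and 1121 and 1014 called by DESeq2.

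**Figure D3:**
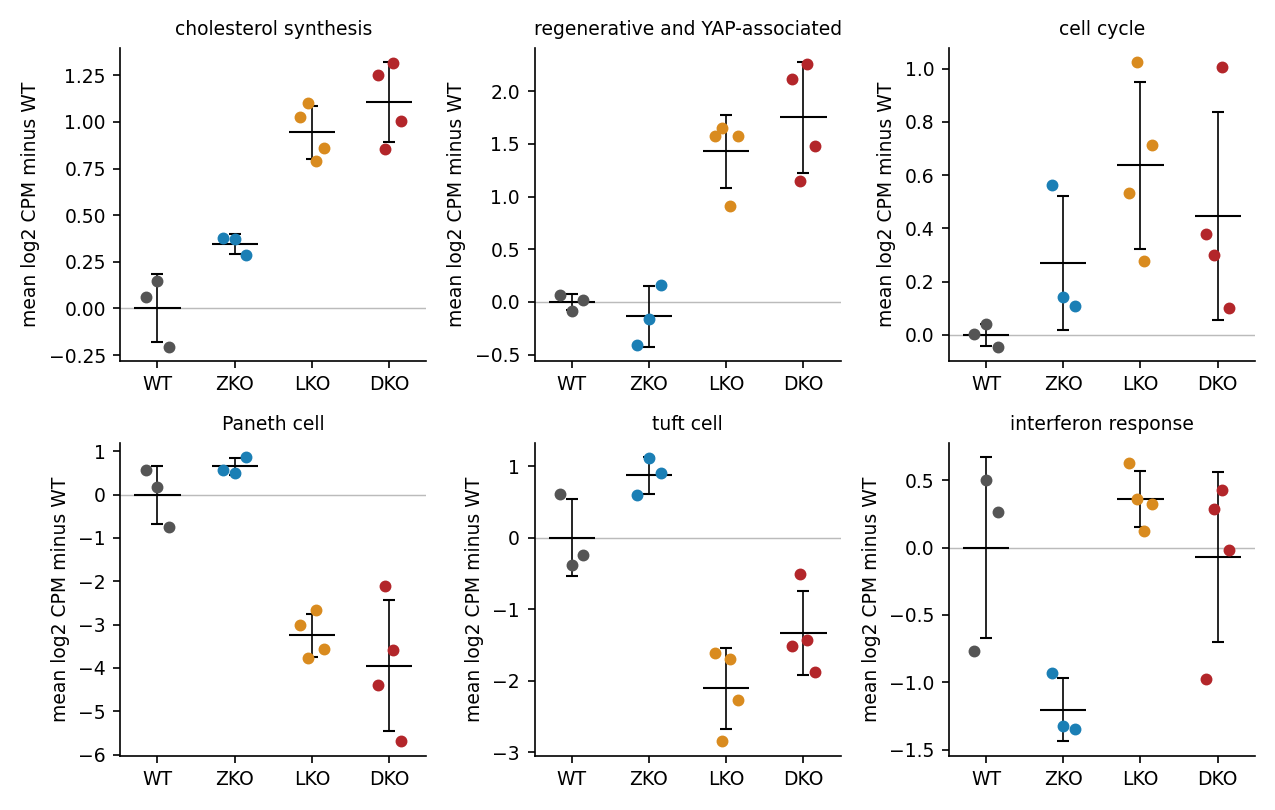
Scores of 6 gene lists in each library (mean log2 CPM of the members minus the WT mean, linear axes that differ between panels); dots are libraries and the lines with bars are the group mean ± SD. The Paneth score lies between -5.70 and -2.10 in LKO and DKO and between -0.74 and 0.87 in WT and ZKO, and the interferon score between -1.35 and -0.93 in ZKO.

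The responses were then compared with each other. Of the genes that differed from WT, 428 rose in both DKO and LKO, where independence gives 43.7, and 197 fell in both, where independence gives 21.8. Across the 13432 genes, which are not independent replicates, the log2 changes of DKO and LKO had a Pearson correlation of 0.78 and a covariance of 0.460. In 20 simulations of unchanged groups set against the same WT libraries these were 0.56 and 0.0626, where genes vary independently of each other, and 0 genes were called in both. DKO and ZKO shared 2 genes that rose, Mt1 and Ces1f, where independence gives 0.473. They shared 5 that fell, Amph, Tifa, Ptk6, Gpr160 and Reg3b, where independence gives 0.6; Amph and Gpr160 were named after their values were seen. The log2 changes of DKO and ZKO had a correlation of 0.26 and a covariance of 0.105, against 0.52 and 0.0631 in the simulations. With the WT libraries divided between the comparisons, 1 for one and 2 for the other, the covariance of DKO and LKO was 0.360 to 0.435 over the 6 divisions and that of DKO and ZKO was 0.00284 to 0.0763. A single WT library left fewer calls, and the shared genes numbered 0 to 126 for DKO and LKO and 0 to 3 for DKO and ZKO. Without the 3 tilted libraries 141 genes were called in the same direction in DKO and LKO, against 1364 with a term for the tilt. For DKO and ZKO these counts were 41 and 25. With a term for Y-linked reads DKO and ZKO shared 1 gene, and without the 3 libraries that hold such reads edgeR called 0 in both, against 54 by DESeq2 in all libraries. The count for DKO and LKO, 625 in all libraries, was 225 without WT_216, 235 without WT_254 and 245 without WT_259, and that for DKO and ZKO was 17, 3 and 4.

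The interaction (DKO minus LKO minus ZKO plus WT) addresses whether the 2 losses add up on the log2 scale. WT alone lacks Cre, so a change that Cre brings to all 3 other groups also gives an interaction, of the opposite sign. A difference that sex or colony brings to ZKO alone would do the same. Y-linked reads were present in ZKO_19, ZKO_20 and DKO_240 and in no WT or LKO library. Mt1 was at 53.8 ± 9.52 CPM in WT and 532 ± 20.4 in ZKO (n = 3 each), and at 550.1 ± 24.6 in LKO and 714 ± 318 in DKO (n = 4 each). Its change in DKO was less than the sum of both single changes, with an interaction of -2.93 (SE 0.41, adjusted p = 0.0165). Ces1f, at 12.9 CPM in WT, 58.5 in ZKO, 55.6 in LKO and 41.5 in DKO, had an interaction of -2.60 (SE 0.33, adjusted p = 0.0165), and Abhd3 of -1.75 (SE 0.24, adjusted p = 0.0165). Lgi4, Pxdn and 1700003D09Rik, named after their values were seen, had -4.88, -5.93 and -3.96 (adjusted p = 0.0165, 0.0283 and 0.0442). The interferon list had a positive interaction in 55 of 56 members. Their median log2 change was 0.91 (adjusted p = 9.5e-13, or adjusted p = 0.528 with an estimated correlation). The MHC class I list (0.45, adjusted p = 2.1e-06 and 0.350 with an estimated correlation) was positive as well, and the stem cell list (-0.48, adjusted p = 5.6e-09 and 0.338) negative.

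By the edgeR test 6 genes had a negative interaction and 0 a positive one. Of the 13432 tested, 817 had an unadjusted p under 0.05, where chance alone gives a share of about 0.05. DESeq2 called 14 positive and 61 negative, limma-voom 0 and 4, and limma-voom with sample quality weights 16 and 33. The count was 1 without WT_259, 3 without ZKO_22, 15 without LKO_224 and 25 without DKO_231. It was 0 without WT_216, WT_254, ZKO_19, LKO_250 or DKO_260. None of the calls of Mt1, Ces1f and Abhd3 held without each library in turn (adjusted p up to 0.0926, 0.0854 and 0.0926, without WT_259). Besides these 3 lists, 13 passed with the preset correlation, and 0 of the 16 did with an estimated correlation.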

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

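The tests of crypt recovery and of the Mt1 and Mt2 ratio were chosen only after the result was seen. The interferon response list score was lower in ZKO than in WT by a difference of -1.20 (SE 0.395). The difference was -1.51 (SE 0.473) with a term for Y-linked reads, -1.15 (SE 0.414) with the T cell list score as a covariate and -1.42 (SE 0.339) with a term for the short-transcript tilt. Each stayed more than 2 SE below 0, which argues against sex, T cell content and the tilt as the whole cause. Loss of PKCζ may lower interferon genes, and a separate colony or litter, which the mouse numbers of ZKO leave possible, stays open and untested. DKO, which also lost PKCζ, scored -0.07 ± 0.63 and LKO 0.36 ± 0.21 (mean ± SD, n = 4 each). The list thus did not pass in DKO against WT, and it was lower in DKO than in LKO with the preset correlation only. The scores of WT_216 (-0.77) and DKO_223 (-0.97) lay near those of ZKO, so the list also varies between libraries of other groups. Both were tilted toward short transcripts, and the term for the tilt had a coefficient of -0.646 (SE 0.272), although LKO_224, also tilted, scored 0.63. Whether mouse or tilt lowered these scores cannot be told apart.

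Paneth and tuft cell list scores were lower in the mean of LKO and DKO than in WT, by -3.60 (SE 0.624) and -1.72 (SE 0.353). With the proximal and distal list scores as covariates the differences were -3.48 (SE 0.682) and -1.40 (SE 0.396), and with a term for the tilt -3.58 (SE 0.658) and -1.68 (SE 0.346). These values argue against the length of intestine sampled and the tilt as the whole cause, as far as the covariates capture them. The list scores can themselves change with genotype. The term marks only WT_216, LKO_224 and DKO_223, but the trend with transcript length was graded. It was -0.015, 0.076 and -0.103 in DKO_231, DKO_240 and DKO_260, and 0.121, 0.171 and 0.163 in LKO_250, LKO_251 and LKO_256. In WT_254 and WT_259 it was 0.195 and 0.226. Members of the stem cell list differed by a median of 0.022 (SD 1.03, 13 positive and 13 negative). Cell cycle scores relative to WT were 0.64 ± 0.31 (mean ± SD, n = 4) in LKO and 0.45 ± 0.39 (n = 4) in DKO. A poorer recovery of crypts would lower stem cell genes about as much as Paneth genes. Taken over the lists, these values argue against it as the whole cause of the Paneth fall. Single members moved apart: Cd44 rose in DKO, while Olfm4 was down in LKO (-1.86) and Tnfrsf19 (-2.12) and Axin2 in DKO. Lgr5 and the stem cell list were also lower in DKO than in ZKO, so a part in the fall stays open. A loss of Paneth and tuft cells, or lower expression within them, after loss of PKCλ/ι may underlie the pattern, and bulk RNA does not separate these.

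Mt1 was higher than in WT in each group with Villin-Cre. In LKO and DKO Mt2 rose along, with a difference in log2 CPM of 3.03 (SE 0.403), which is consistent with induction of metallothioneins. In ZKO the log2 ratio of Mt1 to Mt2 was 4.08 (SE 0.326) above WT and Mt2 differed by -0.76 (SE 0.486), which argues against a joint induction there. A Cre transgene that carries Mt1 sequence could add reads; 7 of 11 libraries with Cre had a ratio above every WT library, all of ZKO and LKO among them and none of DKO. Since a rise of Mt2 hides such reads in the ratio, this source cannot be told apart from regulation of Mt1, and the labels do not describe the transgene.

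A library stood far from the other 3 of its group in 8 of 122 sets of 4 values by Dixon's ratio at its 95% critical value, where chance gives about 1 in 20. The MHC class I list score of DKO_231 was 0.155, against -0.143 to -0.111 in the others. The brush border score of LKO_251 was 0.142, against -0.837 to -0.730, and its regenerative score 0.911, against 1.58 to 1.65. The Spearman trend with transcript length was -0.433 in LKO_224, against 0.121 to 0.171. Log2 CPM of Anxa1 in LKO_251 was 2.33, against 4.74 to 5.08, and that of Sypl2 was 1.26, against -1.11 to -0.93. Log2 CPM of Atg9b in DKO_240 was 5.22, against 3.0 to 3.21, and that of Lpo was 1.35, against -1.02 to -0.69.

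The interaction passed the threshold in 6 genes, where WT alone lacks Cre and no test separated Cre from the loss of the kinases: Ces1f (-2.60), Abhd3 (-1.75), Lgi4 (-4.88), Mt1 (-2.93), Pxdn (-5.93) and 1700003D09Rik (-3.96). Among the lists, the median interaction was positive for interferon response (0.91), MHC class I (0.45), enteroendocrine cell (0.44), proximal small intestine (0.36), regenerative (0.36), T cell (0.71), immediate early (0.25) and oxidative phosphorylation (0.23). It was negative for Paneth cell (-0.76), goblet cell (-0.41), stem cell (-0.48), cell cycle (-0.47), distal small intestine (-0.20), gastric-type (-0.20), cholesterol synthesis (-0.16) and glutathione (-0.45). With an estimated correlation these 16 lists had adjusted p-values from 0.259 to 0.745.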

How the results depend on the processing

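Chosen after seeing the data were lowering every value by 1 and the fits that add a term for, or leave out, the 3 tilted libraries or the 3 with Y-linked reads, as were all alternatives for the shared counts. Without the Y-linked libraries ZKO keeps a single library, assumed to vary like the other groups. The called named genes kept their direction in each alternative run. Of the named genes' values under the alternatives chosen before, single libraries aside, 1243 kept their side of the threshold, 80 lost it and 4 gained it, and without a single library 1192 kept it, 393 lost it and 1 gained it; under those added later 882 kept it and 232 lost it. List results kept direction and side in 380 cases under the former, with 191 that lost the threshold and 29 that gained it. Under the latter 648 kept both, 67 lost the threshold, 23 gained it and 12 turned direction. Without a single library 1061 kept both, 105 lost the threshold, 55 gained it and 4 turned direction. Another pseudocount was not applicable to the gene tests, since the values are counts, and the fit of 2 groups alone was not applicable to the interaction. List scores and other log2 CPM values depend on the prior count, and another prior count was not tried for them. Genes with few counts, such as Anxa10 and Cyp1a1 in WT, are where depth limits a value. A threshold, a left-out library or a smaller fit changes by construction which libraries and genes enter. Fewer libraries alone do not explain counts that rose, such as 531 genes in DKO against LKO without DKO_231, against 7 in all libraries. The causes of such moves were not tested. Counts written with an exponent are rounded to 2 digits.

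The counts of genes that moved by over 1.5 times were as follows. A fit of the 2 groups alone gave 243 higher and 147 lower in DKO against WT, 41 higher and 65 lower in ZKO against WT and 0 higher and 0 lower in DKO against LKO. That setting also gave 316 higher and 387 lower in DKO against ZKO. A term for the tilt gave 2190 higher and 1863 lower in DKO against WT, 1127 higher and 703 lower in LKO against WT and 20 higher and 35 lower in ZKO against WT. Further counts there were 183 higher and 171 lower in DKO against LKO and 1101 higher and 1024 lower in DKO against ZKO. The 3 tilted libraries left out gave 447 higher and 380 lower in DKO against WT, 121 higher and 80 lower in LKO against WT and 22 higher and 108 lower in ZKO against WT. That setting also gave 0 higher in DKO against LKO and 8 positive in the interaction. A term for Y-linked reads gave 629 higher and 488 lower in DKO against WT, 3 higher and 0 lower in ZKO against WT and 0 higher in DKO against LKO. The 3 libraries with Y-linked reads left out gave 239 higher and 149 lower in DKO against WT, 1 higher and 0 lower in ZKO against WT and 0 higher and 1 lower in DKO against LKO. That setting also gave 0 higher and 11 lower in DKO against ZKO and 0 negative in the interaction. A 2-fold threshold gave 585 higher and 452 lower in DKO against WT and 367 higher in LKO against WT. An adjusted p under 0.1 gave 1720 higher and 1512 lower in DKO against WT, 969 higher and 614 lower in LKO against WT and 15 higher and 18 lower in ZKO against WT. That setting also gave 83 higher and 85 lower in DKO against LKO and 1220 higher and 1138 lower in DKO against ZKO. DESeq2 gave 1053 higher and 530 lower in LKO against WT, 55 higher and 112 lower in ZKO against WT and 215 higher and 229 lower in DKO against LKO. Further counts there were 1121 higher and 1014 lower in DKO against ZKO and 14 positive and 61 negative in the interaction. Limma-voom with sample quality weights gave 2364 higher and 2387 lower in LKO against WT, 453 higher and 601 lower in ZKO against WT and 19 higher and 24 lower in DKO against LKO. That setting also gave 16 positive and 33 negative in the interaction. Limma-voom gave 5 lower in DKO against LKO. Every value lowered by 1 gave 3 negative in the interaction.

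Genes called in the same direction in DKO and LKO against WT, 625 in the first analysis, numbered 269 with a fit of the 2 groups alone, 1364 with a term for the tilt, 141 with the 3 tilted libraries left out, 2.2e+02 with the 3 libraries with Y-linked reads left out, 404 with a 2-fold threshold, 1160 with an adjusted p under 0.1, 1108 with DESeq2 and 1793 with limma-voom with sample quality weights; over the 6 divisions of the WT libraries they numbered 90, 126, 0, 0, 22 and 14. Genes called in the same direction in DKO and ZKO against WT, 7 in the first analysis, numbered 15 with a fit of the 2 groups alone, 25 with a term for the tilt, 41 with the 3 tilted libraries left out, 1 with a term for Y-linked reads, 0 with the 3 libraries with Y-linked reads left out, 14 with an adjusted p under 0.1, 54 with DESeq2 and 285 with limma-voom with sample quality weights; over the 6 divisions of the WT libraries they numbered 3, 1, 0, 0, 1 and 0. The log2 change of Prkcz passed the threshold at -1.47 in ZKO against WT with a fit of the 2 groups alone, -1.46 in ZKO against WT with DESeq2, -1.01 in LKO against WT with limma-voom with sample quality weights and -1.59 in ZKO against WT with limma-voom with sample quality weights. Of the 25 lists, camera with the preset correlation called 12 in DKO against WT, 10 in LKO against WT, 16 in ZKO against WT, 16 in DKO against LKO, 12 in DKO against ZKO and 16 in the interaction. A term for the tilt called 10 in ZKO against WT. An estimated correlation called 1 in DKO against WT, 1 in LKO against WT, 0 in ZKO against WT, 0 in DKO against LKO, 0 in DKO against ZKO and 0 in the interaction. Directional fry called 4 in DKO against WT, 5 in LKO against WT, 2 in ZKO against WT, 0 in DKO against LKO and 0 in the interaction. Mixed fry called 19 in DKO against WT, 5 in ZKO against WT, 3 in DKO against LKO, 20 in DKO against ZKO and 1 in the interaction.

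With a term for the tilt, the direction turned for oxidative phosphorylation in ZKO against WT (adjusted p = 0.217). With the 3 tilted libraries left out, the direction turned for interferon response in LKO against WT (adjusted p = 0.0326) and oxidative phosphorylation in ZKO against WT (adjusted p = 0.600). With a term for Y-linked reads, the direction turned for cell cycle in ZKO against WT (adjusted p = 0.264), enterocyte brush border in ZKO against WT (adjusted p = 0.00299), B and plasma cell in ZKO against WT (adjusted p = 0.0648) and oxidative phosphorylation in ZKO against WT (adjusted p = 0.552). With the 3 libraries with Y-linked reads left out, the direction turned for goblet cell in ZKO against WT (adjusted p = 0.0217), B and plasma cell in ZKO against WT (adjusted p = 0.0289), stroma, endothelium and nerve in ZKO against WT (adjusted p = 5.6e-05), stroma, endothelium and nerve in DKO against ZKO (adjusted p = 0.00237) and regenerative and YAP-associated in the interaction (adjusted p = 0.813). Leaving out each library in turn, counts ranged over 321 to 1601 higher and 252 to 1487 lower in DKO against WT, 178 to 946 higher and 112 to 637 lower in LKO against WT and 3 to 16 higher and 0 to 39 lower in ZKO against WT. They ranged over 0 to 277 higher and 0 to 2.5e+02 lower in DKO against LKO, 220 to 1107 higher and 268 to 1113 lower in DKO against ZKO and 0 to 4 positive and 0 to 21 negative in the interaction. Without each WT library, shared counts were 225 to 245 for DKO and LKO and 3 to 17 for DKO and ZKO. The log2 change of Prkcz ran from -1.03 to -0.65 in LKO against WT. The adjusted p of lists whose direction turned without a single library ran from 4.7e-06 to 0.738 for B and plasma cell in ZKO against WT, 0.000524 to 0.643 for oxidative phosphorylation in ZKO against WT, 6.9e-06 to 0.953 for T cell and intraepithelial lymphocyte in DKO against LKO and 0.0337 to 0.933 for myeloid cell in DKO against LKO.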

Other observations

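The splits of the libraries below were counted only after the result was seen. A library of LKO and one of DKO lay between the groups. LKO_251 and DKO_231 had the highest Prkcz of their groups, at 71.5 and 43.0 CPM, and the lowest regenerative list scores, at 0.91 and 1.15. Their tuft cell scores were -1.70 and -0.50, and their Paneth cell scores of -2.67 and -2.10 were the highest of their groups.

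Other splits of the same libraries into groups of the same sizes were fitted with the 2 groups alone. In DKO against WT the real split called 390 genes and 2 of 35 splits called as many, with 1056 as the highest other, so this count does not exclude chance. In LKO against WT it called 949 genes, against 1906 as the highest of the others, with 2 of 35 as large, and in DKO against ZKO 703 against 922, with 2 of 35, which does not exclude it either. The single larger split in each moved 1 in-between library (DKO_231 with WT, LKO_251 with WT and DKO_231 with ZKO), which points to a structure of the samples, and the next highest called 0, 0 and 5. In DKO against LKO each of the 35 splits, the real one included, called 0 genes by edgeR, so the count says nothing about chance; the fit of all libraries had 1794 at an unadjusted p under 0.05 and DESeq2 called 444. ZKO against WT allows 10 splits, too few for a share under 0.05, with 106 genes in the real split and 1 as the highest other. For the interaction 3 of 100 drawn regroupings of all libraries called at least the real 6 genes, with 125 as the highest other, but these mix the difference between the groups with and without Prkci into the spread and decide nothing. With labels exchanged only between WT and ZKO and between LKO and DKO, 4 of 100 drawn regroupings called at least 6, with 14 as the highest other, but breaking up ZKO and WT removes the difference between them, which the interaction holds, so this decides nothing either. With WT and ZKO kept and labels exchanged between LKO and DKO alone, 8 of 70 regroupings called at least 6, and 9 of the 69 others called 0. The difference between ZKO and WT stays in each of these regroupings and can itself give calls. This scheme therefore does not decide, and chance stays open. The highest other, 154, placed LKO_224, LKO_251, LKO_256 and DKO_231 together as DKO and points to a structure of the samples. The count of 6 fell to 0 without WT_216, WT_254, ZKO_19, LKO_250 or DKO_260.

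Alleles that flank a targeted gene and differ between the groups could change genes near it. Within 10 Mb of Prkci, 3 of 51 genes (5.88%) had an unadjusted p under 0.05 in ZKO against WT, against 8.14% elsewhere (one-sided Fisher's exact p = 0.796). Within 10 Mb of Prkcz, 32 of 127 genes (25.2%) did in LKO against WT, against 23.5% elsewhere (one-sided Fisher's exact p = 0.363). At the adjusted threshold 1 gene near Prkci and 6 near Prkcz were called, of 15 and 881 called in all. A p that misses the threshold excludes nothing, and the 95% intervals of the odds ratios, 0.14 to 2.19 and 0.708 to 1.65, leave room for such genes, so the absence that the test was set to show was too weak a bound and the explanation cannot be told apart from its absence.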
